A study of Arabidopsis thaliana and Lambdavirus lambda with 138 samples.

How the data were processed

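The series covers MBD5, MBD6 and SLN in Arabidopsis thaliana by several assays. Used here were the bisulfite PCR libraries, the enzymatic methyl-seq library of lambda DNA, and the lists of hypervariable bins, C-DMRs and loci that were deposited with a whole-genome bisulfite library. The DAP-seq, ChIP-seq, whole-genome bisulfite, RNA-seq and GRO-seq measurements were not analysed here. Per the labels' protocols, plants grew on soil in long days. Inflorescence DNA of batch 1 was extracted with a column kit and leaf DNA of batch 2 with CTAB. DNA for bisulfite PCR went through 2 rounds of conversion and was amplified with Pfu Turbo Cx, and the products of a sample were pooled before library construction. Per the labels, the lambda DNA was purchased, methylated with M.SssI and made into a library by enzymatic conversion.

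For bisulfite PCR, the deposited files gave for each cytosine the methylated read count and the total read count, and the fraction that the authors computed as their ratio. For lambda DNA, the deposited files gave the percent methylated at each cytosine with its read counts, in 1 file per context. The deposited lists hold positions or locus identifiers and no other measurement. Per the file names, the larger locus list and the smaller are named for earlier studies by Zhang and by Schmitz and their colleagues, and the bins carry a name that refers to their standard deviation, whose values were not used here. The submitters' processing notes name build TAIR10 and the tools BSMAP, Bismark, Trim Galore, Bowtie2, Picard, deepTools 3.0.2, STAR and HTSeq, with no role for each. Which aligner, caller and filters made the bisulfite PCR and lambda files is not given in the sources used here.

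All values were computed from the read counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A cytosine entered with at least 10 reads in a library, and 6 of 1350 site values in the bisulfite PCR had fewer, each with 3 reads or fewer, at the edge positions 13038143, 13038357 and 13038568 in batch 2. The level of a region and context in a library was the mean of its cytosine levels, each weighted equally. Groups came from the sample titles. The labels name no molecular identifiers for the PCR reads, which are then not independent molecules, so intervals and limits cover counting error only. Nothing says that the replicates of batch 1 came from separate plants, so the spread between these samples may be technical. Their permutation p is fixed by the number of arrangements wherever the groups lie apart, and does not measure that spread.

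The mbd5 mbd6 and Col-0 libraries were compared by a two-sided exact permutation test of library means. The transgene-positive and transgene-negative plants were compared by a two-sided exact permutation test within lines (216 arrangements, smallest p 0.00926), with 95% intervals from inverting the test and Benjamini-Hochberg adjustment over 11 regions and contexts, and per CG cytosine with adjustment over 14 cytosines. The fwa and Col-0 leaf libraries and the lambda library were given exact binomial (Clopper-Pearson) intervals. Tissue, extraction and batch differ together between batches, so no genotype comparison crossed them, apart from the alternative that adds the batch 1 Col-0 libraries.

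Listed genes were matched by identifier to a gene table of assembly TAIR10.1 with 37887 nuclear genes, used only for names, classes and which gene a position falls in or near. Its coordinates are not printed. Of 681 gene identifiers in the larger list 678 matched, and of 53 in the smaller all matched. Gene classes and the overlap of lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 8 classes of a list. Matched gene length used 10000 random draws of genes within length classes, a permutation test. Overlaps of intervals were tested against 10000 random circular shifts within chromosomes, and those with gene classes against 1000. The centromere of a chromosome was taken as the middle of its window of 1 Mb with the fewest protein-coding genes. Gene families could not be tested, since the table holds no descriptions and 29.3% of listed protein-coding genes have a symbol. In the lambda files 24 cytosines stood in 2 context files and were given the context with most reads.

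The genes and cytosines named were chosen by a rule set before the data were examined. It takes the gene at the bisulfite PCR regions, the cytosines of largest and smallest difference, the members of both fixed gene lists that have a bin or are listed, up to 25 shared genes that have a symbol, the 10 genes of the larger list with the most bins, and up to 3 members of each class past the test. Cytosines named beyond the single largest and smallest, and the tests by cytosine that passed without adjustment, were added after the values were seen. The alternatives set beforehand were coverage minimums of 1 and 100 reads, pooled reads, cytosines that pass the minimum in every library of a comparison (in batch 1 all do, so nothing moved there), correction for CHH, blocks by replicate or none by line, line means, each library or line left out, other Col-0 or fwa groupings, other list backgrounds and other overlap widths. Chosen after the data were seen were the count of plants 24 and 25 as 1, matched gene length for the fixed gene lists, and another context rule at lambda flanks. The tests were also tried on simulated data. In 50 simulations the class test called a class 3 times as frequent in 100% and the shift test called 10 planted overlaps in 100%, and with none planted 4% and 6% were called.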

Results

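DNA methylation was measured by bisulfite PCR in 3 regions in and beside FWA in 18 Arabidopsis thaliana libraries. FWA (AT4G25530) encodes a homeodomain transcription factor, and in wild-type vegetative tissue its tandem repeats are methylated and the gene is silent. Library batch 1 held inflorescence DNA from 2 Col-0 (wild-type) replicates and 2 replicates of the mbd5 mbd6 double mutant, which lacks a pair of methyl-CpG-binding domain proteins. Library batch 2 held rosette leaf DNA from 1 Col-0 library, 1 library of fwa, a late-flowering epiallele with unmethylated FWA, and 12 T2 plants in the fwa background from lines 12, 23 and 52 of a ZF108-SLN transgene. ZF108 is an artificial zinc finger that binds FWA, and SLN (SILENZIO) is a J-domain protein. Each line gave 2 transgene-positive and 2 transgene-negative siblings, 6 plants per group. In addition, 1 library of lambda phage DNA treated with the CpG methyltransferase M.SssI was profiled by enzymatic methyl-seq, and lists of loci with variable DNA methylation were examined.

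The bisulfite PCR reported cytosines of the minus strand in 3 regions of chromosome 4 (TAIR10). Region 1 ran from 13038143 to 13038272 with 3 CG and 20 CHH cytosines. Region 2 ran from 13038357 to 13038499 with 6 CG, 2 CHG and 21 CHH cytosines. Region 3 ran from 13038568 to 13038695 with 7 CG, 1 CHG and 17 CHH cytosines. By the gene table, region 1 lay outside the annotated FWA gene, region 2 spanned its end nearest to region 1, and region 3 lay inside it. Of the 77 cytosines, 25 lay outside the annotated gene. Reads per cytosine ranged from 3081 to 15951 in batch 1 and from 1645 to 25775 in batch 2. A count of 0 allowed a level of up to 0.182% at the lowest depth and 0.0116% at the highest.

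Loss of MBD5 and MBD6 was compared with wild type to see whether methylation of FWA itself differed in the mutant. FWA stayed densely CG methylated in mbd5 mbd6, at 88.3% ± 0.886 (SD, n = 2) over the 3 regions against 91.5% ± 0.0236 (SD, n = 2) in Col-0, and the mean fell by 3.21 percentage points. Non-CG methylation was higher in the mutant. CHH methylation was 4.69% ± 0.0625 (SD, n = 2) against 2.15% ± 0.0893 (SD, n = 2), a ratio of 2.18, and CHG methylation was 17.1% ± 0.885 (SD, n = 2) against 13.4% ± 0.709 (SD, n = 2), a ratio of 1.28. In all 3 regions and every context present in them, the mutant libraries lay apart from the Col-0 libraries.

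The CG difference was largest in region 2, where the level was 85.2% ± 1.33 (SD, n = 2) in mbd5 mbd6 and 91.1% ± 0.0879 (SD, n = 2) in Col-0. In region 1 the levels were 88.9% ± 0.886 and 90.8% ± 0.675, and in region 3 they were 90.7% ± 0.504 and 92.2% ± 0.160 (SD, n = 2 each). The CHH difference was largest in region 1, with 6.96% ± 0.0727 in the mutant and 1.91% ± 0.0245 in Col-0, a ratio of 3.65. The CHH ratios were 1.63 in region 2 and 1.38 in region 3. CHG levels were 21.8% against 17.4% in region 2 and 7.69% against 5.32% at the 1 CHG cytosine of region 3.

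Both mutant libraries lay below both Col-0 libraries at 13 of 16 CG cytosines, above them at 1 and overlapped them at 2. For a single cytosine chance gives 16.7% in each direction. Cytosines read in the same libraries are not independent, so these counts are not a test of the genotype. The mutant libraries lay above Col-0 at 3 of 3 CHG and 55 of 58 CHH cytosines, with overlap at the other 3 CHH cytosines. The largest CG difference was at position 13038357, with 90.4% and 89.5% in the Col-0 libraries against 74.1% and 80.6% in the mutant libraries. Its neighbour at 13038361 fell by 8.16 percentage points, and the next, at 13038364, fell by 7.65. Position 13038357 is the first of region 2 and an edge position with few reads in batch 2. Without the edge positions, region 2 CG was 86.3% and 87.3% in the mutant libraries against 91.1% and 91.5% in Col-0. Over the 3 regions it was 88.7% and 89.6% against 91.6% in both. The smallest CG difference, 0.0219 percentage points, was at 13038250. The largest CHH difference was at 13038246 in region 1, with 8.25% and 8.04% in Col-0 and 28.5% and 28.1% in mbd5 mbd6. The CHH cytosines at 13038245, 13038240 and 13038253 followed, with gains of 14.9, 14.4 and 14.3 percentage points.

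With 2 libraries against 2, the two-sided exact permutation test gave p = 0.333 for each region and context, the smallest p the 6 arrangements allow, so no difference could pass 0.05 in this test. The differences were 2.44 to 93.1 times the pooled SD of the libraries, smallest for region 1 CG and largest for region 1 CHH. Fisher's exact test on the reads, which compares these libraries and not the genotypes, passed a false discovery rate of 0.05 at 13 CG cytosines, all lower in the mutant, and at 3 CHG and 52 CHH cytosines, all higher. When CHG levels were corrected for the CHH level of the same library, the CHG difference was 3.13 percentage points in place of 4.39 in region 2, 1.74 in place of 2.37 in region 3, and 1.54 in place of 3.71 over the 3 regions, where the CHH of region 1, which has no CHG, is also subtracted. This correction takes all CHH signal as failed conversion, so it also subtracts any true CHH methylation. With reads pooled, the region 1 CG difference was -1.26 in place of -1.92.

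**Figure D1:**
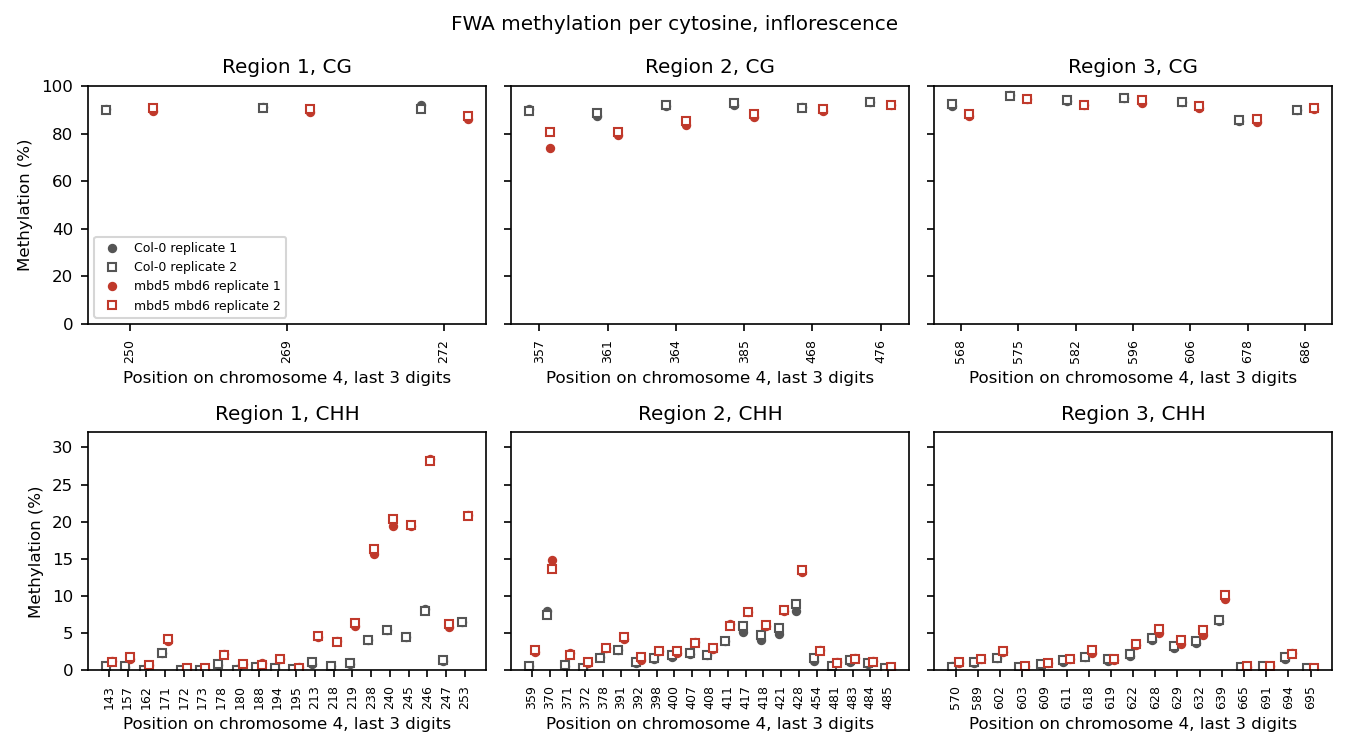
Methylation in percent (y axis) of each CG and CHH cytosine of the 3 FWA regions (x axis, last 3 digits of the position on chromosome 4) in inflorescence, with grey points for the 2 Col-0 libraries and red points for the 2 mbd5 mbd6 libraries, circles for replicate 1 and squares for replicate 2. The red points lie below the grey at the CG cytosine 13038357 (74.1% and 80.6%) and above them at the CHH cytosine 13038246 (28.5% and 28.1%).

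The rosette leaf libraries showed the epigenetic states of FWA that the transgene experiment starts from. In the fwa library, CG methylation was 0.105% in region 1, 0.486% in region 2 and 0.0634% in region 3, where the Col-0 library had 89.9%, 87.3% and 84.8%. Over the 3 regions, CG methylation was 0.223% in fwa and 86.8% in Col-0, CHG methylation 0.0893% and 17.3%, and CHH methylation 0.138% and 6.99%. With reads pooled over cytosines, the exact binomial 95% intervals were 0.294% to 0.359% for fwa CG and 86.5% to 87.0% for Col-0 CG, for counting error only. The 6 transgene-negative plants, which share the fwa background, had CG levels of 0.167% to 0.275% over the 3 regions. With 1 library per genotype there was no replicate check, and no test was made. Correcting for CHH moved the difference of fwa from Col-0 in CHG from -17.2 to -11.1 percentage points over the 3 regions, from -20.6 to -13.6 in region 2 and from -10.4 to -3.48 in region 3. That correction takes all CHH signal as failed conversion. The fwa library of the same batch had 0.138% CHH, so in Col-0 the correction may mostly subtract methylation. Adding the Col-0 libraries of batch 1 moved the CHH difference over the 3 regions from -6.85 to -3.63.

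Transgene-positive and transgene-negative siblings were compared to see whether ZF108-SLN changed methylation at an unmethylated FWA. No region or context passed the test, and FWA stayed close to unmethylated in both groups. CG methylation over the 3 regions was 0.232% ± 0.0224 (SD, n = 6) in positive plants and 0.220% ± 0.0379 (SD, n = 6) in negative plants. The difference was 0.0126 percentage points (95% interval -0.0329 to 0.0582), with an exact permutation p of 0.509 within lines and an adjusted p of 0.934 over 11 comparisons. With reads pooled it was 0.00638, and corrected for CHH it was -0.000295. The interval excluded a gain in mean CG methylation over 0.0582 percentage points under the test's assumption of a constant shift. The highest CG level of any region among the 13 libraries of the fwa background was 0.642%, in region 2. The level of that region rested on the cytosine at 13038385, whose median over these libraries was 2.17% (range 1.76% to 2.85%), and which was named after its values were seen.

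Region 1 had the smallest p for CG. Its level was 0.129% ± 0.0331 in positive plants and 0.0864% ± 0.0277 in negative plants (SD, n = 6 each), higher in positive plants in 3 of 3 lines by the line means, with an exact permutation p of 0.0556 and an adjusted p of 0.611. The difference of 0.0426 percentage points (95% interval -0.00116 to 0.0889) did not pass. Its unadjusted exact permutation p was 0.0185 without positive plant 12, 0.0278 without positive plant 45, 0.0463 with reads pooled and 0.0346 with lines ignored. It was 0.278 without line 52, where the difference was 0.0268, and 0.25 with line means, the smallest these allow. Over the other removals of a plant or line the unadjusted exact permutation p ran from 0.0556 to 0.157. Corrected for CHH, the difference was 0.00152 percentage points. Region 1 CHH was 0.199% ± 0.0549 in positive and 0.158% ± 0.0249 in negative plants, with an exact permutation p of 0.185, and of 0.0463 unadjusted without positive plant 12. The region 1 CHH difference was 0.129 percentage points in line 52, 0.0188 in line 12 and -0.0245 in line 23, and without line 52 it was -0.00284 (exact permutation p = 0.944). The other comparisons had adjusted p of 0.764 or more by the same exact test.

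Of the 14 CG cytosines tested singly, 0 passed a false discovery rate of 0.05 in the exact permutation test within lines. At an unadjusted p under 0.05 there were 2 cytosines, 13038582 with an exact permutation p of 0.00926 (adjusted 0.13) and 13038250 with an exact permutation p of 0.037 (adjusted 0.259). The level of 13038582 was 0.0651% in positive and 0.0310% in negative plants, under the CHH means of region 3 (0.0991% and 0.0997%). The largest difference was at 13038250, 0.197% ± 0.0586 in positive and 0.118% ± 0.0319 in negative plants (SD, n = 6 each). The smallest was at 13038575, with 0.0540% and 0.0525%. The cytosine at 13038250 lies where the median read depth of the fwa background steps from 5581 to 9689. Its median level there was 1.94 times that of the other CG cytosines of region 1. Ignoring lines and Fisher's exact test on summed reads each called 1 cytosine, and the Fisher call was 13038250 (adjusted p = 0.00674), a test that treats PCR reads as independent molecules. A change at 1 cytosine alone could not pass, since 0.00926 is the smallest exact permutation p that the 216 arrangements allow, and 3 cytosines at that p are needed. In 50 simulations per size, gains of 0.1 percentage points at 7 cytosines were recovered in 66.9% of cases, gains of 0.5 points at 7 cytosines in 100% and gains of 5 points at 1 cytosine in 4%. The simulated plants of a group shared a single rate per cytosine and differed by counting error only. These shares may therefore be higher than real plants allow.

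In reads per cytosine, negative plants 24 and 25 of line 23 gave a chi-square of 57.4 (73 degrees of freedom, p = 0.910). In the same chi-square test, 31 of 32 replicate pairs of the same group had p under 0.05. A read covers many cytosines of a region, so the 74 cytosines are not independent and these p-values do not measure sampling noise. Among the 78 pairs of libraries of the fwa background, 3 other pairs were not under 0.05 either, among them the fwa library with negative plant 17. Plants 24 and 25 had equal reads at 0 cytosines. They were kept as separate plants. Counted as 1 plant, the exact permutation p for region 1 CG was 0.12, and no call changed.

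**Figure D2:**
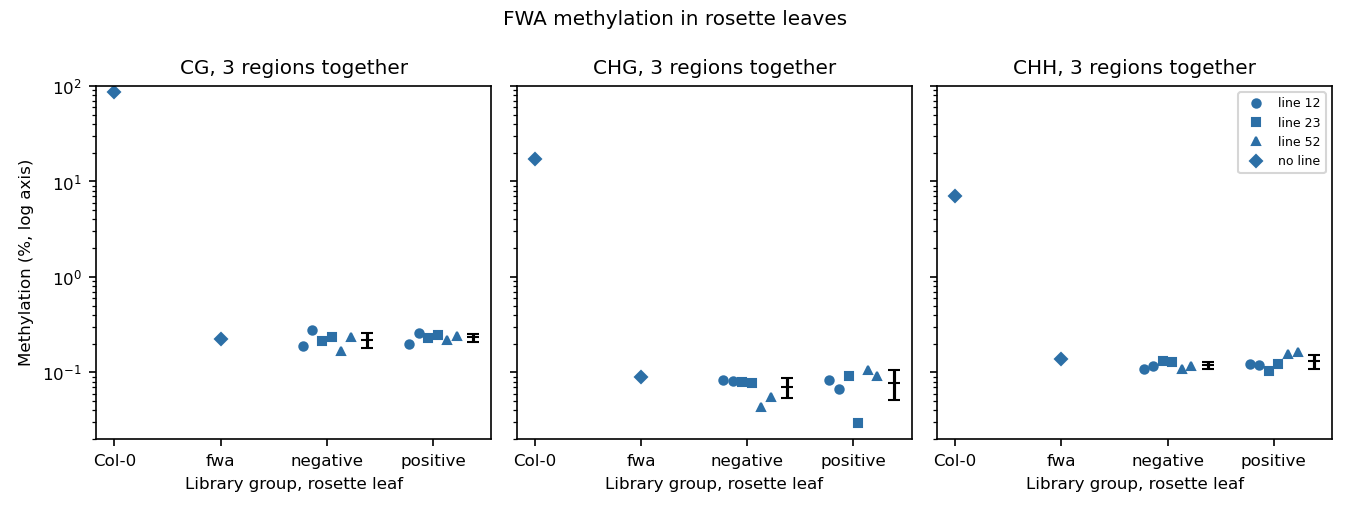
Methylation in percent (y axis, log scale) over the 3 FWA regions in rosette leaf, per context, for the Col-0 library, the fwa library and the 6 transgene-negative and 6 transgene-positive plants (x axis), with a marker shape per line and black bars for mean ± SD. The CG level is 86.8% in Col-0, 0.223% in fwa, and 0.167% to 0.275% in the negative plants.

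The M.SssI-treated lambda DNA showed CG methylation close to complete and little methylation elsewhere. Over 6209 CG cytosines, 97.6% of reads were methylated (exact binomial 95% interval 97.5% to 97.6%). Over 6442 CHG cytosines the level was 1.20% (1.14% to 1.25%), and over 11456 CHH cytosines it was 0.192% (0.177% to 0.209%). The median depth was 25 reads per cytosine in each context, and this is 1 library with no replicate. The CHG methylation was concentrated, since 121 CHG cytosines above 20% held 79.5% of the methylated CHG reads, and the level without them was 0.250%. At 11 CG cytosines the level was 50% or lower, and 10 of these had 1 read. Among symmetric CHG pairs, which hold a CHG cytosine on each strand, 66 had a cytosine above 20%, and 65 of these had CHH cytosines on both flanks.

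**Figure D3:**
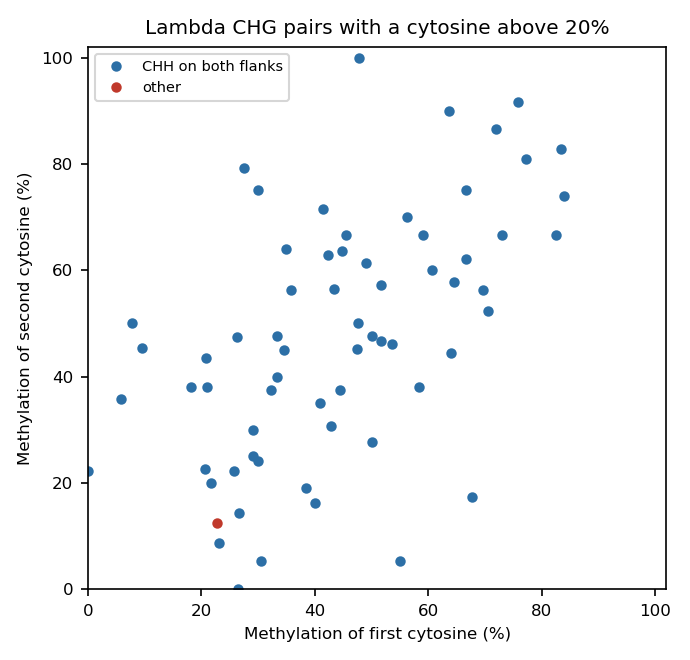
Methylation in percent of both cytosines of each of the 66 symmetric CHG pairs of lambda DNA with a cytosine above 20% (x axis, first cytosine, and y axis, second cytosine), with blue points for the 65 pairs with CHH cytosines on both flanks and a red point for the remaining pair. The median of the pair means is 47.2%, and in 64 pairs both cytosines are above 5%.

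The lists of variable loci held 4554 hypervariable bins of 100 bp and 72 C-DMRs, differentially methylated regions of 36 to 1064 bp with a median of 174 bp. The larger locus list held 1790 identifiers, 1109 transposable elements (62.0%) and 681 genes, of which 678 matched the gene table. The smaller held 123 identifiers, 70 transposable elements and 53 genes, all matched. All 678 matched genes of the larger list had a bin within 500 bp of the gene. The list held 226 of the 226 genes with bins near both ends, 452 of the 1745 with bins near a single end, and 0 of the 1897 with bins inside only. FWA was in neither list and had no bin or C-DMR within 500 bp.

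Both gene lists shared 23 genes and 23 transposable elements. Chance would give 0.949 shared genes (odds ratio 43.5, two-sided Fisher's exact p = 1.69e-26). The odds ratio was 7.98 with genes within 1 kb of a bin added to the larger list and 61.1 among protein-coding genes. The shared genes with a symbol were HEI10, a meiotic crossover factor, with 6 bins inside, HDG10, a homeodomain gene of the family of FWA, with 1, NAC105, a NAC transcription factor gene, with 1, and SKP1, a subunit of SCF ubiquitin ligases, ARP6, a subunit of the SWR1 chromatin remodeller, and MYB3R-5, a MYB transcription factor gene, each with 0 inside and 1 within 500 bp. Of the 72 C-DMRs, 35 (48.6%) overlapped a bin by 1 bp or more, against a mean of 0.883 and a highest count of 8 in 10000 random circular shifts (one-sided permutation p = 0.0001, the smallest these shifts can give). With 50% or more of the C-DMR covered, 16 did, at the same p. All 53 genes of the smaller list had a C-DMR within 500 bp, as all 678 matched genes of the larger had a bin. The overlaps of genes and of intervals are therefore not separate evidence. Neighbouring genes may also share a C-DMR, which Fisher's exact test does not take into account.

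The genes of the larger list with the most bins inside were AT5G47300 with 7, HEI10 with 6, the long non-coding RNA gene AT1G07887, MRD1 and the pseudogene AT2G19200 with 5 each, and AT1G35895, the pseudogene AT1G65750, MEE65 and AT5G11370 with 4 each. AGL85, a MADS-box gene, was the last of the 10, with 3, a count that other genes of the list, such as AT2G08735 and AT4G05815, shared. The longest runs of touching bins had 5 bins each, on chromosome 2 from 8333101 to 8333600 near AT2G19200 and on chromosome 5 from 19198801 to 19199300 near AT5G47300.

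Hypervariable bins lay in protein-coding genes more often than shifted bins did, 71.8% against 56.1% (permutation, adjusted p = 0.0032 over 1000 shifts), and less often in pseudogenes, 3.51% against 9.09% (adjusted p = 0.0032). The C-DMRs lay in protein-coding genes less often, 25% against a shift mean of 59.0% (permutation, adjusted p = 0.0032). Between 35.2 and 40.9 bins per Mb were found on the chromosomes. Within 3 Mb of the centromere lay 20.8% of bins, below the shift mean of 24.9% (permutation p = 0.0062), and 38.9% of C-DMRs, above the shift mean of 24.1% (p = 0.0470). For the bins, the share was also below the shift mean at 1 Mb, 2.90% against 8.30% (permutation p = 0.0002), but not at 5 Mb, 41.1% against 40.4% (permutation p = 0.681). For the C-DMRs it was also above at 5 Mb, 56.9% against 39.3% (permutation p = 0.0326), but not at 1 Mb, 2.78% against 8.05% (permutation p = 0.214). The p-values for distance from the centromere were not adjusted for the number of interval sets and widths tested.

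**Figure D4:**
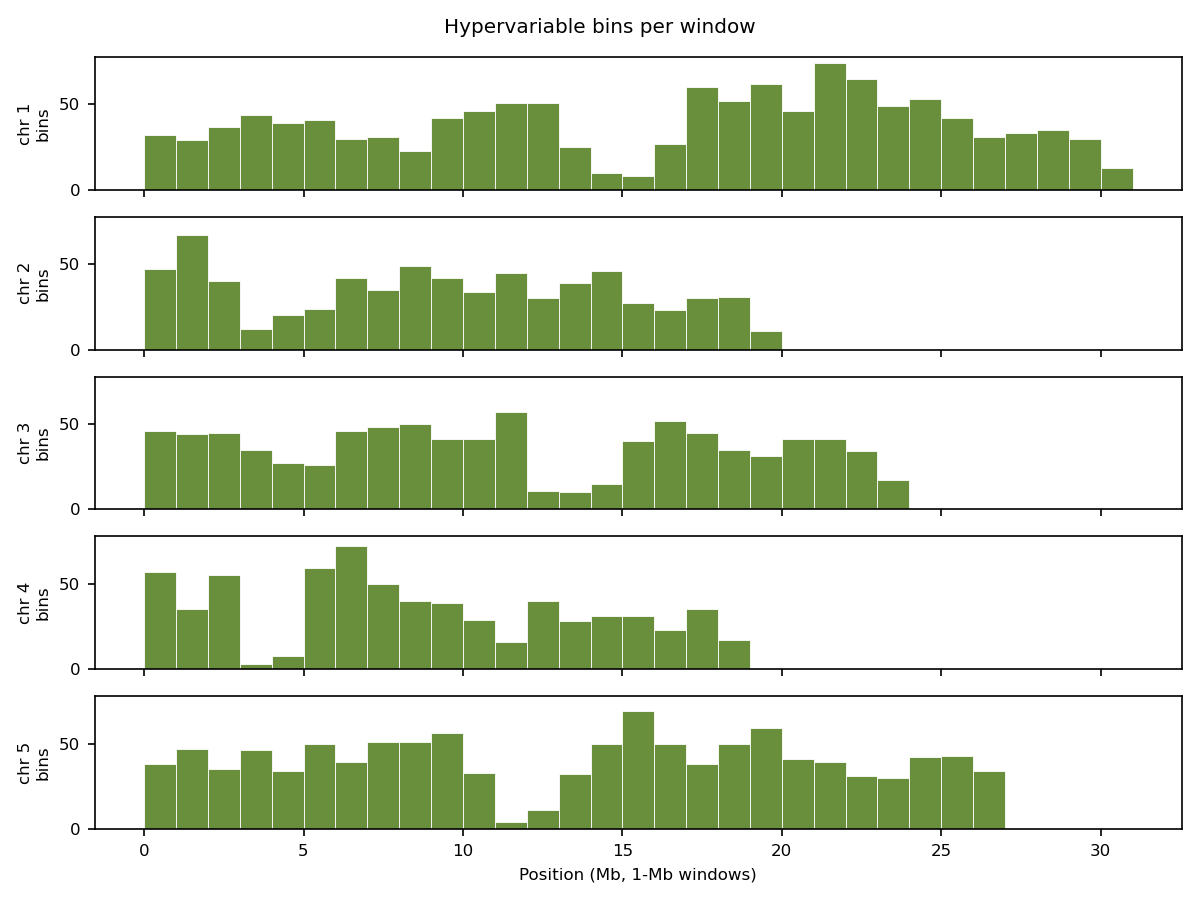
Number of hypervariable bins (y axis) in windows of 1 Mb along each of the 5 chromosomes (x axis, position in Mb), as green bars that start at 0. The highest window, on chromosome 1, holds 74 bins, and the lowest, on chromosome 4, holds 3.

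Among the genes of the larger list, protein-coding genes were fewer and long non-coding RNA genes more frequent than among all annotated genes. Protein-coding genes made up 423 of 678 (62.4%) against 72.4% (odds ratio 0.626, Fisher's exact adjusted p = 9.38e-08), led by AT5G47300, HEI10 and MRD1. Long non-coding RNA genes made up 107 (15.8%) against 9.19% (odds ratio 1.88, Fisher's exact adjusted p = 1.17e-07), led by AT1G07887, AT2G08735 and AT4G05815. There were 12 microRNA genes (odds ratio 2.12, Fisher's exact adjusted p = 0.036), with MIR426, MIR413 and MIR397a among them, and 7 antisense RNA genes (odds ratio 5.38, adjusted p = 0.00145), with AT4G03675, AT1G08427 and AT2G09035 among them. All of these calls ended against a background of matched gene length, where the ratios of observed to expected were 0.967, 1.13, 1.28 and 3.24, with adjusted permutation p of 0.375, 0.375, 0.49 and 0.107. Among the 3025 genes with a bin inside, in place of the list, protein-coding genes were more frequent (2815 genes, odds ratio 5.58, Fisher's exact adjusted p = 5.49e-194) and long non-coding RNA genes less frequent (odds ratio 0.235, adjusted p = 7.84e-53). These odds ratios were not matched for gene length, and a longer gene has more room for a bin. Of the bins themselves, 1.84% lay in long non-coding RNA genes, against a shift mean of 1.78% (permutation, adjusted p = 0.823).

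In the smaller list, 27 of 53 genes were protein-coding (odds ratio 0.395, Fisher's exact adjusted p = 0.00402), led by AT5G47300, HEI10 and HDG10, and the call ended with matched gene length (ratio 0.803, permutation, adjusted p = 0.15) and among genes with a C-DMR inside (odds ratio 0.448, adjusted p = 0.0656). Other non-coding RNA genes numbered 6 of 53, 11.3% against 1.93% (odds ratio 6.52, Fisher's exact adjusted p = 0.00402), with AT2G00840, AT1G07507 and AT1G09215 among them. This call held among genes with a C-DMR inside (odds ratio 6.17, Fisher's exact adjusted p = 0.0442) and with matched length (ratio 4.46, permutation, adjusted p = 0.0288).

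Of 28 genes fixed beforehand for methylation-dependent expression, only QQS, an orphan gene that affects starch content, was in the larger list, with 2 bins inside, and 0 were in the smaller list (Fisher's exact adjusted p = 0.529 for the larger). A bin lay inside 6 of them (Fisher's exact adjusted p = 0.122, with 5.21 expected at matched length), namely QQS, the F-box gene SDC, the resistance genes SNC1 and RPP4, the tryptophan biosynthesis gene PAI3 and the homeodomain gene HDG9. Of 22 genes of DNA methylation and demethylation, 0 were in either list. A bin lay inside 9 of these, the histone methyltransferase genes KYP, SUVH5 and SUVH6, the demethylase genes DME and DML2, the RNA polymerase genes NRPD1 and NRPE1, and DCL3 and MBD5, with 3 bins in DME, 2 in DML2 and 1 in each of the others. This exceeded the share of all protein-coding genes (10.3%, Fisher's exact adjusted p = 0.000713 over the 4 list tests), but these are long genes with a median of 5230 bp against 2078 bp, and 5.42 were expected at matched length (permutation, adjusted p = 0.253, a background chosen after the data were seen).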

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

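The test of the range over lines was chosen after the result was seen. Transgene-negative plant 16 of line 52 had the lowest CHG level of region 2 in its group, 0.0304%, and stood apart from the next plant at 0.0804%. It was the only such sample in 22 groups of 6 plants, where chance gives about 1 in 20.

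For CHH methylation in region 2 and over the 3 regions together, the difference of positive from negative plants went opposite ways in lines 12 and 23, in every plant. This was not so in region 1 or region 3 alone, and in region 3 the difference was negative in both lines (-0.00596 and -0.00788). In region 2 it was 0.0111 percentage points in line 12, -0.0135 in line 23 and -0.00224 in line 52, a range of 0.0246 (exact permutation p = 0.0556). Over the 3 regions it was 0.00857 in line 12, -0.0155 in line 23 and 0.0457 in line 52, a range of 0.0612 (exact permutation p = 0.0556). Neither range passed 0.05, with 11 regions and contexts examined.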

How the results depend on the processing

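The count of plants 24 and 25 as 1, the matched gene length for the fixed lists and the other context rule at lambda flanks were chosen after the result was seen, and the other alternatives before. Outside the removal of single libraries and lines, 214 of 271 values recomputed kept their direction and side of the threshold, or stayed within their spread. Of the others, 29 moved by more, 16 changed direction, 7 no longer passed and 5 newly passed. For each value not kept, the cause was not tested unless stated.

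In mbd5 mbd6 against Col-0 every alternative kept the direction. With reads pooled the region 1 CG difference was -1.26, and the CHH difference was 4.84 percentage points in region 1 and 2.40 over the 3 regions. Corrected for CHH, which subtracts more from the mutant by construction, the CHG difference was 3.13 in region 2, 1.74 in region 3 and 1.54 over the 3 regions. With a library left out, CG differences ranged from -2.55 to -1.29 in region 1, -6.81 to -4.93 in region 2, -1.84 to -1.13 in region 3 and -3.84 to -2.58 over the 3 regions. CHG differences ranged from 3.61 to 5.16 in region 2, 2.04 to 2.70 in region 3 and 3.09 to 4.34 over all. CHH differences ranged from 5.00 to 5.10, 1.55 to 1.74 and 0.606 to 0.792 in regions 1, 2 and 3, and from 2.48 to 2.61 over all. The labels do not say whether libraries with the same replicate number share anything else. Across cytosines, same-numbered libraries deviated with a correlation of 0.000245, or -0.307 in CG and 0.678 in CHG and CHH, and cytosines are not independent. The replicate block left the CG difference at -3.21 over the 3 regions, with an exact permutation p of 0.5, the smallest it allows, and changed no call.

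In the positive against negative comparison, differences near 0 changed sign. With a minimum of 1 read, region 2 CG was 0.0178. Corrected for CHH, region 2 CG was 0.000778, all CG -0.000295 and all CHG -0.00519. Region 1 CG passed an unadjusted exact permutation test with reads pooled (0.0499) and with lines ignored (0.0426). The count of single CG cytosines was 1 with lines ignored and 1 by Fisher's test on summed reads, against 0. With a plant or line left out, the ranges were 0.0268 to 0.0560 for region 1 CG, -0.00284 to 0.0738 for region 1 CHH, -0.0400 to 0.0384 for region 2 CG, -0.0155 to 0.0323 for region 2 CHG, -0.00786 to 0.00442 for region 2 CHH, 0.00149 to 0.0146 for region 3 CG, -0.0209 to 0.0131 for region 3 CHG and -0.00692 to 0.00412 for region 3 CHH. Over all regions they were -0.00151 to 0.0268 for CG, -0.0129 to 0.0208 for CHG and -0.00345 to 0.0271 for CHH. Of these values 178 were kept across both genotype and transgene comparisons, 28 changed sign and 3 passed unadjusted.

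In fwa against Col-0 every alternative kept the direction. With reads pooled the differences were -89.1 for region 1 CG, -4.98, -9.04 and -7.67 for CHH in regions 1, 2 and 3, and -83.8 for region 3 CG. Corrected for CHH, which takes all CHH signal as failed conversion, they were -85.8 for region 2 CG, -83.7 for region 3 CG and -85.7 for all CG. For CHG they were -13.6 in region 2, -3.48 in region 3 and -11.1 over all. With the Col-0 libraries of both batches they were -90.4, -89.3, -89.7 and -89.7 for CG in regions 1, 2, 3 and all, -18.4, -6.98 and -14.6 for CHG in regions 2, 3 and all, and -2.89, -4.37, -3.54 and -3.63 for CHH in regions 1, 2, 3 and all.

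The lambda CG level was 97.4% as a mean over cytosines. The odds ratio of the list overlap was 7.98 with genes within 1 kb added. C-DMRs overlapping a bin over 50% or more of their length numbered 16. The pericentromere ratio was 1.02 for bins at 5 Mb and 0.345 for C-DMRs at 1 Mb. Among genes with a bin inside, the odds ratios of the larger list turned to 5.58 for protein-coding genes, 0.231 for pseudogenes, 0.235 for long non-coding, 0.0364 for transfer, 0.178 for micro, 0.454 for antisense and 0.270 for other non-coding RNA. The odds ratio of small nuclear or nucleolar RNA genes was 0.906 in the list and 0.0622 among genes with a bin inside, where it newly passed (Fisher's exact adjusted p = 7.69e-11). The odds ratios among genes with a bin inside were not matched for gene length. With matched gene length the ratios were 0.967, 1.13, 0.782 and 0.799 for protein-coding, long non-coding, transfer and other non-coding RNA genes, and 0.803 and 0.681 for protein-coding and transfer RNA genes of the smaller list. Among genes with a C-DMR inside the odds ratio of protein-coding genes was 0.448, no longer past the threshold. For the 22 methylation genes the ratio was 1.66 at matched length. Lambda strands, a stricter standard deviation for bins and protein-coding backgrounds for families were not run, as the values they need are not given in the sources used here. Depth limits single cytosines of the fwa background, where a count of 0 allows up to 0.182%.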

Other observations

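The tests of explanations and the count over splits in this part were chosen after the result was seen. Col-0 FWA had more CHH methylation in rosette leaf than in inflorescence. At the cytosines common to both batches, the leaf library had 5.38%, 8.21% and 7.28% CHH methylation in regions 1, 2 and 3. The inflorescence libraries had 1.96% and 1.99% in region 1, 2.53% and 2.71% in region 2, and 1.78% and 1.94% in region 3. CG methylation over the 3 regions was 86.8% in leaf and 91.6% in both inflorescence libraries. Tissue, batch and extraction differed together, with 1 leaf library, so these cannot be told apart.

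In mbd5 mbd6, FWA had less CG and more CHG and CHH methylation than Col-0. Incomplete conversion, if even over cytosines, was argued against as the whole source. The 14 CHH cytosines lowest in Col-0 gained a median of 0.218 percentage points and at most 1.25, while the mean gain of all CHH cytosines was 2.54. Conversion that fails more at some cytosines than at others would not be seen by this comparison and stays open. The largest CHH gains, 12.0 to 20.2 percentage points, were at 13038238, 13038240, 13038245, 13038246 and 13038253 in region 1. In the 13 libraries of the fwa background their median levels were 0.241% to 0.469%. At 13038247 the median was 0.368% and the gain 4.69. The other region 1 CHH cytosines had medians of 0.0377% to 0.189%. In Col-0 the cytosines of largest gain were also the highest of region 1 CHH, 4.04% to 8.14%, so this does not decide. Admixture of unmethylated FWA as the whole source was argued against by the CHG ratio of 1.278, and by CG ratios of 0.925 and 0.946 in region 2 against 0.980 and 0.988 in region 3, which leave a smaller shared loss open. An effect of the genotype may be the cause. The exact permutation p of 0.3333 is fixed by the design and decides nothing, and as no label separates genotype from plant lineage or reaction, these cannot be told apart.

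A single CG cytosine of region 2, at 13038385, had a median level of 2.17% (1.76% to 2.85%) in the 13 libraries of the fwa background, 31.8 times the median of the other CG cytosines of the region. Carry-over of methylated template was argued against, since those other cytosines had a median of 0.06834%. The cytosine lies where the read depth steps from 4750 to 12754, so a read edge is a candidate cause. The 4 other depth steps had ratios of 0.871 to 1.973, which neither match it nor exclude an effect of sequence at this edge, so it cannot be told apart from a property of the site. A first definition of a step found 1 edge only, this one, and the second was set afterwards from depth alone, and no biological explanation was tested.

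In the lambda DNA, CHG methylation at few cytosines is consistent with dcm methylation, which modifies CCWGG in common Escherichia coli hosts. Of 66 symmetric CHG pairs with a cytosine above 20%, 65 (98.48%, exact binomial 95% interval 91.8% to 100.0%) had CHH cytosines on both flanks, as CCWGG needs, against 306 of all 2406 pairs (12.7%, two-sided Fisher's exact p = 5.69e-60). An even failure of conversion or even off-target M.SssI was argued against as the whole source, as the CHG level was 6.209 times the CHH level. Without the 121 CHG cytosines above 20%, the CHG level was 0.250% against 0.192% for CHH, so an even background at the rest stays open. Off-target M.SssI that differs between CHG and CHH was not tested. The lambda sequence was not used here, so the motif itself was not read.

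For the 14 CG cytosines of positive against negative plants, the real count past the threshold was 0, so 100 of 100 splits within lines gave as many by construction (highest other count 0), and the splits decide nothing.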
